A study of Homo sapiens with 17 samples.

How the data were processed

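Bulk RNA was extracted from aggregates of H9 human embryonic stem cells with a column kit (Bioline Isolate II) and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The 16 bulk libraries fall into 8 time points with 2 replicates each, and the labels gave both the time and the replicate number. The labels give no sequencing batch. For the single-cell library, 20 organoids were dissociated and cells were captured with a droplet kit (Chromium Single Cell 3' v3.1), per the labels' protocols.

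The deposited bulk table holds whole-number read counts per gene, as the authors counted them, without normalization. Per the submitters' processing notes, reads were converted with bcl2fastq 2.17 and aligned with STAR 2.7.9a to GRCh38. The annotation, the counting tool and the strand setting are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies may therefore be shared or lost, and levels of such genes are uncertain. Of many overlaps among the genes the results name, PAX6 overlaps ELP4, POU5F1 overlaps TCF19, SOX10 overlaps POLR2F, DLL1 overlaps FAM120B and RARB overlaps TOP2B, each on the other strand, and NEUROD1 overlaps CERKL, KRT7 overlaps KRT86 and EGLN3 overlaps SPTSSA on their own strand in GENCODE 29. The count table names 39295 gene symbols, of which 39160 (99.7%) matched 1 gene of that annotation, which gave the coordinates. No row lacked a gene name.

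For the single-cell library only a table with values per cell was used. The authors' deposited values are counts of UMIs and of detected genes per cell, the fraction of UMIs from mitochondrial genes and the fraction of genes with no UMI, a size factor given as a ratio with a mean of 1, and a cluster number. Per the submitters' processing notes DRAGEN was used and the genome was hg38. UMI and gene counts before some genes were removed are the ones reported, with a median of 5050 UMIs per cell against 4828 after removal. All cells were marked as singlets by the authors (0 were not), so no doublet caller was run. The lowest cell had 501 UMIs and the highest mitochondrial share was 9.99%. Shares of cells have 95% exact Clopper-Pearson intervals, which cover counting error only.

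Total counts per bulk library ran from 15821806 to 27678337. Folds of genes with few counts are limited by counting. A gene with no count in a group is given as a bound, computed against 3 counts over the group, and a gene with 1 to 3 counts as a ratio with a 95% exact counting interval. PCR copies were not removed by molecular identifiers in the bulk libraries, so these intervals and bounds cover counting error only.

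Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on time point, which left 17168, and library sizes were scaled with TMM factors. A quasi-likelihood model (glmQLFit) with 1 coefficient per time was fitted to all 16 libraries, since 2 replicates per time give little information on the spread by themselves. Each later time was tested against 0h and each time against the one before with glmQLFTest (13 comparisons, two-sided), with Benjamini-Hochberg adjustment over the genes within a comparison and a threshold of 0.05. A joint F-test of the 7 time coefficients asked which genes varied at all. Standard errors are the fold change divided by the square root of F. Principal components were computed on log2 CPM with a prior count of 2. The replicates of each time were compared by a chi-square test of their counts.

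Gene lists were fixed before the data were examined, as were the tests and the rule for naming genes. There are 30 lists with 364 different genes, of which 24 fell below the count filter. They cover stem cells (pluripotency, naive pluripotency), neural tissue (neuroectoderm, forebrain and eye field, midbrain, hindbrain and spinal cord, neurons, neural crest and placode), other cells (non-neural ectoderm and amnion, mesendoderm, endoderm, mesenchyme) and signalling (immediate early, YAP and SRF targets, Nodal and TGF-beta, BMP, FGF and ERK, WNT, Notch, retinoic acid). The rest cover stress and metabolism (heat shock, integrated stress and unfolded protein response, p53, hypoxia and glycolysis, cholesterol synthesis, metallothioneins and zinc export, mitochondrial genome, ribosomal proteins) and cell structure (cell cycle, epithelial junctions, basement membrane). A few genes belong to more than 1 list, such as TDGF1 and GDF3 to pluripotency and Nodal targets. Lists with at least 5 tested members were tested against the other genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists. The same test was repeated with the correlation estimated from the data. That repeat was stricter also where the members did not move together. Neuroectoderm at 1d, with an estimated correlation of −0.05, went from a camera adjusted p = 2e-10 to 0.0024. A list lost in the repeat is therefore not shown to hold genes that move together.

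Named genes are, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Names of clones and of some non-coding families were left out, and names with a dot, which drops hyphenated symbols since the table writes hyphens as dots. Per list up to 4 called members with the smallest adjusted p and up to 2 others with the highest CPM are also named, and any list member may be. From these sets the text names a part, and a few genes are not reported here. STC2, TRIB3, RPS27, CHAC1, RAX and SIX6 are given per library because their replicates stood apart, a choice made after their values were seen.

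Alternatives planned beforehand were RLE factors, scaling by library size alone, no filter on low counts, a filter of at least 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, the 4 libraries of a comparison alone, DESeq2 1.42.0 and the estimated correlation. Added after seeing the data were fits on the 6 libraries of 0h, 1h and 6h, with and without the block, removal of each library's trend with transcript length or GC content (lowess span 0.3), and omission of 3 libraries together. Those 3 are 1d replicate 2, which has a GC trend against its partner, and 6d replicate 1 and 8d replicate 1, which are low in ribosomal protein transcripts. Removing a trend also removes any true change that follows length or GC content. Single cells were also filtered to at least 2000 UMIs, and to under 10% mitochondrial UMIs. No permutation of time labels was made, since groups of 2 libraries allow too few splits.

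The fits were tested on simulated counts with the real library sizes and dispersions and a single mean per gene over all libraries. In these, 200 genes with a mean of at least 5 CPM were changed. No other gene changed over time, so the recovery need not hold for the real comparisons. For 1h against 0h (16741 genes tested) edgeR recovered 63% of 2-fold and 97% of 4-fold changes and called 13 unchanged genes. For 8d against 0h (16742 genes) it recovered 63% and 99% and called 8. DESeq2 recovered 80% and 100% with 39 unchanged genes called, and 78% and 99% with 32, over 17168 genes. Figures were drawn with matplotlib 3.10.9 and intervals computed with SciPy 1.17.1 in Python 3.11.15 and with R.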

Results

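Aggregates of H9, an established human embryonic stem cell line, were sampled while they differentiated into an early neural organoid, a cultured tissue that forms brain-like neuroepithelium. RNA of whole aggregates was sequenced at 0h, 1h, 6h, 1d, 2d, 4d, 6d and 8d, with 2 replicates at each of the 8 time points, which gave 16 bulk libraries. A separate single-cell library was made from 20 organoids pooled at 8d. The comparisons ask which genes departed from their level at 0h at each of the 7 later times, and which changed from one time to the next. Total counts ran from 15821806 (0h replicate 1) to 27678337 (6d replicate 1) per library, and 20118 to 21660 genes had a count. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

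The time course was the main axis of variation. The first principal component of the bulk libraries held 63.8% of the variance and ran from −81.8 (1h replicate 2; the 0h replicates were at −74.7 and −80.4) to 105.2 at 8d, and the second held 11.9%. Replicates differed by more than sampling noise at every time (chi-square per degree of freedom between 5.92 at 2d and 94 at 6d), so no pair looked like 1 library given again. This does not show that the replicates were separate cultures. The 6d pair was the least alike, with a Pearson correlation of log2 CPM of 0.965 across genes and 6d replicates at 53.3 and −34.8 on the third component. Mitochondrially encoded RNA took between 3.01% of counts (1d replicate 2, whose partner had 6.18%) and 7.21% (0h replicate 1).

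Over all times, 8904 of 17168 tested genes (51.9%) varied in edgeR's quasi-likelihood F-test of the 7 time coefficients, at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2331 had their highest mean at 8d and 1999 their lowest. The highest mean was at 1d, 2d or 4d for 2022 genes (22.7%), which can be among those lowest at 8d. Errors on log2 fold changes below are standard errors, and errors on CPM (counts scaled to library size) are SDs of the 2 libraries of a time (n = 2). Adjusted p-values of single genes come from edgeR's test over all tested genes. Those of gene lists come from camera, adjusted over 30 lists that were fixed in advance.

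**Figure D1:**
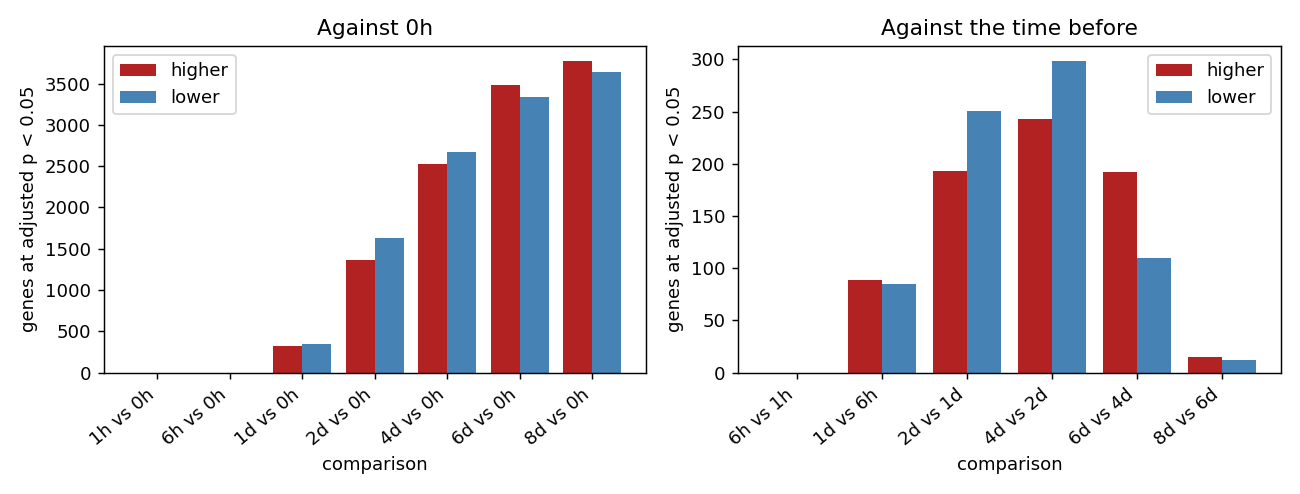
Genes called higher (red) or lower (blue) at an adjusted p under 0.05 in edgeR's test; the y axis counts genes and the x axis names the comparison, against 0h on the left and against the time before on the right. Against 0h the count grew from 0 at 1h and 6h to 3767 higher and 3636 lower genes at 8d, while the step from 6d to 8d had 15 higher and 12 lower.

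Within the first 6 hours no single gene passed edgeR's test on all 16 libraries, and no gene list passed with an estimated correlation between genes. At 1h camera passed 15 targets of YAP and SRF, regulators of transcription that respond to cell shape and serum, as higher (adjusted p = 0.0062). With an estimated correlation camera's adjusted p was 0.99, and 2 of the 15 were higher at an unadjusted p under 0.05 in edgeR. CCN2, a matricellular protein, was at 31.9 ± 4.1 CPM against 15.6 ± 2.1 at 0h (log2 fold change 1.03 ± 0.26) and CCN1 at 1.09 ± 0.34, both with an adjusted p of 1. At 6h camera passed as higher 10 heat shock genes (adjusted p = 4e-04; HSPA1A 0.66 ± 0.18, HSPA1B 0.74 ± 0.22, DNAJB1 0.52 ± 0.17) and 10 BMP targets (0.031; ID3 0.5 ± 0.31, ID1 0.33 ± 0.44), and as lower 17 cholesterol synthesis genes (4e-06; HMGCS1 −0.58 ± 0.36, SQLE −0.41 ± 0.25) and 12 FGF and ERK targets (0.031). Each of these 4 lists had an adjusted p = 0.78 with an estimated correlation. At an unadjusted p under 0.05, 3 heat shock genes and 0 BMP targets were higher, and 1 cholesterol gene and 2 FGF and ERK targets lower. EGR1, an immediate early gene, was 1.08 ± 0.54 above 0h at 1h, also with an adjusted p of 1. HSPA1A and HSPA1B are near-identical copies, so reads may have been split between them.

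In edgeR's test on all libraries no gene passed at 1h or at 6h against 0h. At 1h 389 genes had an unadjusted p under 0.05, against 858 that chance gives among 17168; at 6h there were 837, and 825 for 6h against 1h, where again no gene passed. DESeq2 called 4 genes at 1h, 0 at 6h and 13 for 6h against 1h, and edgeR with no filter on low counts called 12, 43 and 56. Fits on the 6 libraries of 0h, 1h and 6h, chosen after seeing the data, gave 0, 0 and 3 genes. With the replicate number as a block they gave 12, 149 and 140. Without the block 820, 1738 and 1480 genes had an unadjusted p under 0.05 in them, against 803 that chance gives among 16058. No member of the lists that camera passed, 1 at 1h and 4 at 6h, passed over all genes. Adjusted over the list alone, 1 YAP and SRF target and 3 heat shock genes passed and none of the others, and DESeq2 called 0 members of these lists. The list calls also rested on single libraries. Without 0h replicate 1 the adjusted p was 0.097 for YAP and SRF, 0.14 for BMP and 0.5 for FGF; without 1h replicate 1 it was 0.1 for YAP and SRF. Leaving out 6h replicate 1 gave 0.17 for heat shock, and leaving out 6h replicate 2 gave 0.12 for cholesterol, 0.6 for BMP and 0.64 for FGF.

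By 1d some early neural genes had risen and some epithelial and stem cell genes had fallen. SOX3, a transcription factor of neural progenitors, rose by 2.03 ± 0.21 (adjusted p = 0.00079), and PAX6, a regulator of forebrain and eye development, by 2.09 ± 0.27 (adjusted p = 0.0016). The Notch ligand DLL1 rose by 1.63 ± 0.17 and LFNG, which modifies Notch receptors, by 1.27 ± 0.15. EPCAM, an epithelial adhesion molecule, changed by −1.99 ± 0.22 (adjusted p = 0.00079) and TERF1, a telomere-binding protein abundant in stem cells, by −1.08 ± 0.14. The largest rises included the signalling ligands WNT5B (29.7 ± 2 CPM against 3.13 ± 2.4) and WNT7B (6.67 ± 0.29 against 0.74 ± 0.53) and the nitric oxide synthase NOS2 (23.8 ± 6.8 against 2.44 ± 1.8). SERPINB9, a protease inhibitor, fell from 17.6 ± 8 to 0.935 ± 0.3 CPM. HES5, a Notch effector, was 18.9-fold above 0h, where it had 2 counts (counting interval 4.96 to 161; edgeR adjusted p = 0.011, but 0.17 without 0h replicate 2).

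Among 15 neuroectoderm genes 7 rose and none fell at 1d (9 adjusted over the list alone, camera adjusted p = 2e-10), and of 13 forebrain and eye field genes 3 rose (6 over the list alone, adjusted p = 3e-07). Of 11 Notch pathway genes 3 rose (5 over the list alone, adjusted p = 5.9e-08, but adjusted p = 0.079 with an estimated correlation). Of 16 pluripotency genes 6 fell (1 higher and 6 lower over the list alone, adjusted p = 6e-05, and adjusted p = 0.15 with an estimated correlation). Among 10 genes of epithelial junctions 5 fell (6 over the list alone, adjusted p = 5.9e-08, and adjusted p = 0.086 with an estimated correlation). The lists of WNT targets (2 of 11 rose, adjusted p = 0.011), neural crest and placode (1 of 11 rose, 3 over the list alone, adjusted p = 0.031) and the mitochondrial genome (0 of 9 called by edgeR or DESeq2, 1 at an unadjusted p under 0.05, adjusted p = 0.00091, lower) each had an adjusted p = 0.71 with an estimated correlation. Leaving out 1d replicate 2, the library low in mitochondrial RNA, gave 0.077, 0.28 and 0.67 for these 3, with no WNT or crest gene called; without 0h replicate 1 crest stood at 0.077 with the mitochondrial list at 0.061 and 1 WNT target called. Without 0h replicate 2 the counts were 2 neuroectoderm, 0 forebrain, 1 pluripotency and 1 junction gene and no crest or WNT gene, and without 1d replicate 2 they were 3, 1, 1 and 1. Without 0h replicate 1 there were 4 neuroectoderm and 3 pluripotency genes, and without 1d replicate 1 there were 3 crest and 9 mitochondrial genes. Crest also had 3 without either 4d library and 2 without either 6d library.

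Altogether 670 genes passed at 1d (317 higher, 353 lower; 393 by at least 1 on the log2 scale). This count depended on single libraries. It was 56 without 0h replicate 2, 97 without 1d replicate 2, 404 without 0h replicate 1, 431 and 432 without 1h replicate 1 and 2, 1126 and 1140 without 6d replicate 1 and 2, and 1534 without 1d replicate 1. DESeq2 called 1210 and edgeR with no low-count filter 1805. From 6h to 1d 174 genes passed (89 higher, 85 lower), led by WNT7B (3.53 ± 0.42), NOS2 (3.16 ± 0.42) and WNT5B (2.65 ± 0.36) among the rises. APELA, a peptide hormone of stem cells, fell from 115 ± 1.4 to 13.5 ± 7.3 CPM, a log2 change of −3.07 ± 0.36 (adjusted p = 0.0068). None of these 4 passed without 6h replicate 2 (adjusted p from 0.12 to 0.17) or without 1d replicate 2 (0.056 to 0.082), each of which left 0 genes in this comparison by edgeR's adjusted test (1374 and 1432 at an unadjusted p under 0.05). Other omissions gave 45 genes without 6h replicate 1, 70 and 79 without 1h replicate 1 and 2, 87 and 84 without 2d replicate 1 and 2, 411 and 413 without 6d replicate 1 and 2, and 999 without 1d replicate 1. DESeq2 gave 578 and no low-count filter 1090.

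At 2d some neural genes lay further above 0h than at 1d, and some epithelial genes further below. The median log2 change against 0h was 1.34 for the neuroectoderm list (0.62 at 1d) and −3.69 for epithelial junctions (−1.97 at 1d). The lists were not tested between 1d and 2d. HES5 was 342-fold above 0h (counting interval 94.3 to 2830) and SOX1, a neuroepithelial transcription factor, rose by 5.74 ± 0.58 (adjusted p = 2.8e-05). SOX3 rose by 2.83 ± 0.21, PAX6 by 2.86 ± 0.28 and the Notch ligand JAG1 by 1.52 ± 0.15. EPCAM changed by −4.46 ± 0.26 (adjusted p = 7.9e-07) and CDH1, the epithelial cadherin, by −4.58 ± 0.45 (adjusted p = 2.4e-05). Of stem cell genes, the DNA methyltransferase DNMT3B changed by −2.06 ± 0.16, L1TD1 by −3.63 ± 0.35 and the Nodal co-receptor TDGF1 by −6.82 ± 0.93. Of 11 crest and placode genes 7 rose (camera adjusted p = 1e-05, but adjusted p = 0.21 with an estimated correlation), among them SNAI2 (18.1 ± 0.54 CPM against 0.256 ± 0.29), NGFR (3.49 ± 0.29) and SOX10 (3.62 ± 0.56). SOX10 overlaps POLR2F on the other strand, and counting by strand is not given in the sources used here. NOS2 reached 268 ± 15 CPM and SULF1, a heparan sulfatase, 354 ± 14 CPM against 6.64 ± 3.9 at 0h.

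Of the lists, neuroectoderm had 9 of 15 genes higher at 2d (10 over the list alone, camera adjusted p = 2.2e-15), the Notch pathway 8 of 11 (adjusted p = 4e-18), and forebrain and eye field 7 of 13 higher with 1 lower, HESX1 (8 and 1 over the list alone, adjusted p = 7.7e-05). Epithelial junctions had 7 of 10 lower (adjusted p = 1.4e-11). Those 4 lists held with an estimated correlation. Pluripotency had 10 of 16 lower and 1 higher, FOXD3, which neural crest also uses (adjusted p = 3.8e-07, and adjusted p = 0.062 with an estimated correlation). Of WNT targets 5 of 11 rose, 7 over the list alone, LEF1 by 2.34 ± 0.23 (adjusted p = 0.00089, and adjusted p = 0.48 with an estimated correlation). Of the neuron list 1 of 13 rose, 8 over the list alone (adjusted p = 0.0069, and adjusted p = 0.65 with an estimated correlation). In non-neural ectoderm and amnion 3 of 11 fell, among them the epithelial keratin KRT7 at −4.04 ± 0.24 (adjusted p = 0.0027, and adjusted p = 0.48 with an estimated correlation). Without 0h replicate 2 there were 4 crest genes; without 0h replicate 1, 0h replicate 2 or 2d replicate 2 there were 2 WNT targets. The neuron count was 0 without any 0h or 2d library, 3 without either 4d library and 8 without either 6d library, and FOXD3 did not pass without any 0h or 2d library, while 2 pluripotency genes were higher without either 6d library.

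In all, 2990 genes passed at 2d (1364 higher, 1626 lower; 1770 by at least 1 on the log2 scale); the count was 1460 without 0h replicate 2, and 1575 and 1659 without 2d replicate 1 and 2. From 1d to 2d 444 genes passed (193 higher, 251 lower). HES5 (4.21 ± 0.36), NOS2 (3.5 ± 0.37) and WNT7B (3.21 ± 0.28) were among the rises. The sodium channel subunit SCNN1A fell from 18.1 ± 4.4 to 1.55 ± 0.033 CPM, and PPP1R1B, a phosphatase inhibitor, from 34.4 ± 3.6 to 2.61 ± 1.6. That count was 89 and 101 without 2d replicate 1 and 2, 201 without 1d replicate 2, 750 without either 6d library and 901 without 1d replicate 1. DESeq2 gave 842 and no low-count filter 1441.

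By 4d some stem cell transcripts were low and some neural genes high. POU5F1, the core pluripotency factor OCT4, changed by −7.33 ± 0.73 (adjusted p = 1.2e-05), and ESRG, a non-coding RNA abundant in stem cells, fell from 307 ± 27 to 1.48 ± 0.42 CPM. SOX1 rose by 7.19 ± 0.58 (adjusted p = 2.1e-06), SOX3 by 4 ± 0.22 and BARHL2, a diencephalic homeobox gene, by 7.7 ± 0.59. NR2E1, a receptor of neural stem cells, was 2350-fold above 0h (counting interval 421 to 92800, 1 count at 0h) and HES5 734-fold (203 to 6070). CDH1 changed by −7.11 ± 0.53 and KRT7 by −6.02 ± 0.28. Of 17 genes of cholesterol synthesis 10 fell, with SC5D at −2.04 ± 0.19 and DHCR7 at −1.78 ± 0.34 (camera adjusted p = 6.2e-05, but adjusted p = 0.73 with an estimated correlation). Of 14 genes of the integrated stress response, which is triggered by amino acid shortage or misfolded protein, 7 rose, with DDIT4 at 1.69 ± 0.26 and ATF4 at 0.64 ± 0.13. That list had a camera adjusted p = 0.031, but adjusted p = 0.73 with an estimated correlation, 0.055 without 0h replicate 2 (3 genes higher) and 0.091 without 4d replicate 1 (4 genes).

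Neuroectoderm had 11 of 15 genes higher at 4d (13 over the list alone, camera adjusted p = 3.1e-13), the Notch pathway 10 of 11 (11 over the list alone, adjusted p = 8e-16), pluripotency 11 of 16 lower with FOXD3 higher (adjusted p = 7.1e-10) and epithelial junctions 7 of 10 lower (adjusted p = 2.2e-11); these 4 held with an estimated correlation. The others did not. Forebrain and eye field had 8 higher and 2 lower of 13 (9 and 2 over the list alone, adjusted p = 0.016, and adjusted p = 0.24 with an estimated correlation). Neurons had 7 of 13 higher (8 over the list alone, adjusted p = 0.0025, and adjusted p = 0.75 with an estimated correlation), with MAP2 at 1.31 ± 0.18 and the RNA-binding protein ELAVL4 at 4.75 ± 0.91. Crest and placode had 7 of 11 higher (8 over the list alone, adjusted p = 6.5e-05, and adjusted p = 0.31 with an estimated correlation). Non-neural ectoderm and amnion had 4 of 11 lower (1 higher and 5 lower over the list alone, adjusted p = 0.0051, and adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone, cholesterol synthesis had 16 lower, and the integrated stress list 7 higher and 1 lower. WNT targets had 5 of 11 higher (adjusted p = 0.04, and adjusted p = 0.75 with an estimated correlation).

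Several 4d lists leaned on single libraries. Without 0h replicate 2 the counts were 4 neuron genes, 5 forebrain genes and 2 lower non-neural genes, with 3 WNT targets. Without 4d replicate 1 there were 6 cholesterol genes and 2 lower non-neural genes. Leaving out 4d replicate 2 gave 5 cholesterol genes, 2 WNT targets (adjusted p = 0.32) and 1 lower forebrain gene, and leaving out 0h replicate 1 gave 6 cholesterol genes and 3 WNT targets. Without either 6d library 16 cholesterol genes passed and WNT had an adjusted p = 0.05. FOXD3 did not pass without 0h replicate 2 or 4d replicate 2. Scaling by library size alone gave WNT targets a camera adjusted p = 0.057, a stricter count filter 0.051 and the replicate number as a block 0.063.

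Of all genes 5201 passed at 4d (2530 higher, 2671 lower; 2986 by at least 1 on the log2 scale), and 3209 without 0h replicate 2. Between 2d and 4d 541 passed (243 higher, 298 lower). Scaling by library size alone turned the majority in both, with 54.9% of calls higher against 48.6% for 4d against 0h, and 52.5% against 44.9% for 4d against 2d. RARB, a retinoic acid receptor, rose from 0.963 ± 0.47 to 24 ± 4.8 CPM (4.62 ± 0.38, adjusted p = 0.00013). CYP26A1, of the same pathway list, fell from 7.09 ± 6.6 to 0.445 ± 0.39 CPM (−3.98 ± 0.73, edgeR adjusted p = 0.011). Retinoic acid signalling itself was not tested. The endothelial genes VWF and KDR fell from 28.5 ± 5.5 to 2.4 ± 0.41 and from 24.3 ± 2.8 to 2.28 ± 1.5 CPM, and LMO1, a transcriptional cofactor, from 52.7 ± 8.7 to 2.37 ± 0.89. The count was 149 without 2d replicate 2, 153 without 2d replicate 1, 226 without 4d replicate 2, and 981 and 976 without 6d replicate 1 and 2. DESeq2 gave 971 and no low-count filter 1462.

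At 6d many neuron and crest genes were higher than at 0h and many cell cycle genes lower. Of 13 neuron genes 10 rose (11 over the list alone, camera adjusted p = 6.6e-05, but adjusted p = 0.53 with an estimated correlation), ELAVL4 by 7.08 ± 0.91 and MAP2 by 1.67 ± 0.18, and NEUROD1, a neuronal differentiation factor with no count at 0h, was at least 670-fold higher. SOX10 rose by 4.52 ± 0.57 (106 ± 40 CPM), NGFR by 2.62 ± 0.29 and ETS1 by 3.1 ± 0.51, and 9 of 11 crest and placode genes rose (0.00015, but adjusted p = 0.33 with an estimated correlation). Immediate early genes had 11 of 15 higher (12 over the list alone, 0.0027, but adjusted p = 0.13 with an estimated correlation), including ATF3 (2.87 ± 0.28, adjusted p = 7.7e-06) and BTG2 (3.62 ± 0.5), and the integrated stress list 11 of 14 (12 over the list alone, 0.005, but adjusted p = 0.53 with an estimated correlation), including DDIT3 (1.73 ± 0.29) and HERPUD1 (1.5 ± 0.25). Of 17 cell cycle genes 11 fell (0.0027, but adjusted p = 0.53 with an estimated correlation), among them the kinase BUB1 (−1.44 ± 0.19) and MCM5, a part of the replicative helicase (−0.93 ± 0.12). FN1, fibronectin, rose by 2.04 ± 0.15 (adjusted p = 6.3e-07). Of 10 mesenchyme genes 7 also rose, with POSTN at 4.43 ± 0.66, and 1 fell, and the list did not pass (adjusted p = 0.059, and adjusted p = 0.57 with an estimated correlation); 2 rose without 0h replicate 2.

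Camera's adjusted p at 6d was 2.7e-11 for pluripotency (1 higher, 13 lower; 1 and 14 over the list alone), 5e-09 for neuroectoderm (10 higher, 2 lower; 11 and 2 over the list alone) and 1.6e-11 for the Notch pathway (11 of 11 higher), and these held with an estimated correlation. For epithelial junctions, with 7 lower (8 over the list alone), it was 1.3e-09, and adjusted p = 0.054 with an estimated correlation. Basement membrane (0.014; 5 higher, 1 lower of 12) had an adjusted p = 0.53 with an estimated correlation. So did non-neural ectoderm and amnion (0.0097; 1 higher, 4 lower of 11, 5 lower over the list alone). Cholesterol synthesis (0.0097; 6 of 17 lower, 5 over the list alone) and the mitochondrial genome (0.026; 6 of 9 lower, 8 over the list alone, MT-ND1 at −1.29 ± 0.28) each had an adjusted p = 0.77 with an estimated correlation.

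The 6d libraries differed from each other in several of these groups. CHAC1 and STC2, stress response genes, stood at 62.3 and 114 CPM in 6d replicate 1 and at 13.8 and 22.1 in 6d replicate 2, while NEUROD1 stood at 14.8 and 122. The ribosomal protein gene RPS27 stood at 85.4 and 496 CPM. Without 6d replicate 1 the adjusted p was 0.061 for the stress list (6 genes higher), 0.18 for cholesterol (3 lower), 0.085 for non-neural ectoderm, 0.098 for basement membrane (4 higher, 3 lower) and 0.063 for the mitochondrial genome (2 lower). Without 0h replicate 1 it was 0.058 for basement membrane and 0.085 for the mitochondrial genome (1 lower). The same omission left 7 stress genes, 6 immediate early genes, 7 cell cycle genes and 2 cholesterol genes; without 0h replicate 2 there were 7 stress genes and no lower basement membrane gene. Without 6d replicate 2, 16 cholesterol genes and no basement membrane gene passed as lower. FOXD3, the higher pluripotency gene, did not pass without most single libraries, and the lower neuroectoderm genes numbered 1 without 0h replicate 1 or either 6d library and 0 without 0h replicate 2. With the transcript-length trend removed, chosen after seeing the data, basement membrane and the mitochondrial genome each had an adjusted p = 0.082.

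At 6d 6817 genes passed against 0h (3482 higher, 3335 lower; 3733 by at least 1 on the log2 scale). A fit on the 4 libraries of 0h and 6d gave 3521. Scaling by library size alone moved the median log2 change of all genes from 0.02 to 0.17 and the higher share of calls from 51.1% to 64%. The share was 50.3% with RLE factors, 48.2% with the length trend removed and 48.8% with the GC trend removed. From 4d to 6d 302 genes passed (192 higher, 110 lower). POU3F1, a transcription factor of early neural cells, fell from 99.3 ± 54 to 18.9 ± 7.3 CPM (−2.38 ± 0.32, adjusted p = 0.0058). SST, the peptide somatostatin, rose from 1.84 ± 1 to 54 ± 62 CPM (4.87 ± 0.87, adjusted p = 0.021), so its 6d libraries stood far apart. SST did not pass without 4d replicate 1. The count was 18 without 4d replicate 1, 104 without either 1h library, 109 without either 6h library, 148 and 123 without 2d replicate 1 and 2, 759 without 6d replicate 1 and 1547 without 6d replicate 2. The 4 libraries alone gave 0 genes in edgeR (1173 at an unadjusted p under 0.05), DESeq2 836 and no low-count filter 1605. Library size scaling gave a median of 0.11 and 76.7% higher calls against 63.6%.

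At 8d pluripotency genes were low and neural progenitor genes high. POU5F1 (chromosome 6, 31164337 to 31180731, minus strand) fell from 635 ± 43 to 1.42 ± 2 CPM, a log2 change of −8.65 ± 0.79 (adjusted p = 3.5e-06), and DNMT3B (chromosome 20, 32762385 to 32809356, plus strand) changed by −3.73 ± 0.17. PAX6 (chromosome 11, 31784779 to 31818062, minus strand) rose from 40 ± 12 to 515 ± 95 CPM and SOX1 (chromosome 13, 112067647 to 112070488, plus strand) to 211 ± 14 CPM, by 3.69 ± 0.29 and 8.22 ± 0.59. SOX3 rose from 10.8 ± 2.6 to 243 ± 36 CPM and CDH2, the neural cadherin, went from 383 ± 22 to 1140 ± 52. POU3F3 (chromosome 2, 104855511 to 104858574, plus strand), a neural transcription factor with no count at 0h, stood at 92.6 ± 13 CPM, at least 1040-fold higher. DAZL (chromosome 3, 16586792 to 16670306, minus strand), a germline RNA-binding protein, fell from 24.3 ± 0.39 CPM to no count, at least 350-fold lower. Coordinates are those of GENCODE 29 on GRCh38.

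Of 16 pluripotency genes 14 fell at 8d (15 over the list alone, camera adjusted p = 6.2e-13), including LIN28A (−2.8 ± 0.23), DPPA4 (−2.16 ± 0.16) and SOX2 (−1.09 ± 0.22), the last of which neural progenitors also use. Of 15 neuroectoderm genes 12 rose (adjusted p = 2.7e-10) and 2 fell, LHX5 (−0.82 ± 0.28, adjusted p = 0.033) and SOX21 (−1.36 ± 0.5, adjusted p = 0.043). Without any one of the 0h or 8d libraries neither fall passed, nor did SOX21 without a 1h, 6h, 1d or 2d library. With library size scaling LHX5 had an adjusted p = 0.072 and SOX21 0.066. Of 6 tested naive pluripotency genes 2 rose, with TBX3 at 4.73 ± 0.97, and 2 fell, with KLF4 at −3.36 ± 0.51, and the list did not pass (adjusted p = 0.73). Without 0h replicate 2 only 1 of these rises passed.

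**Figure D2:**
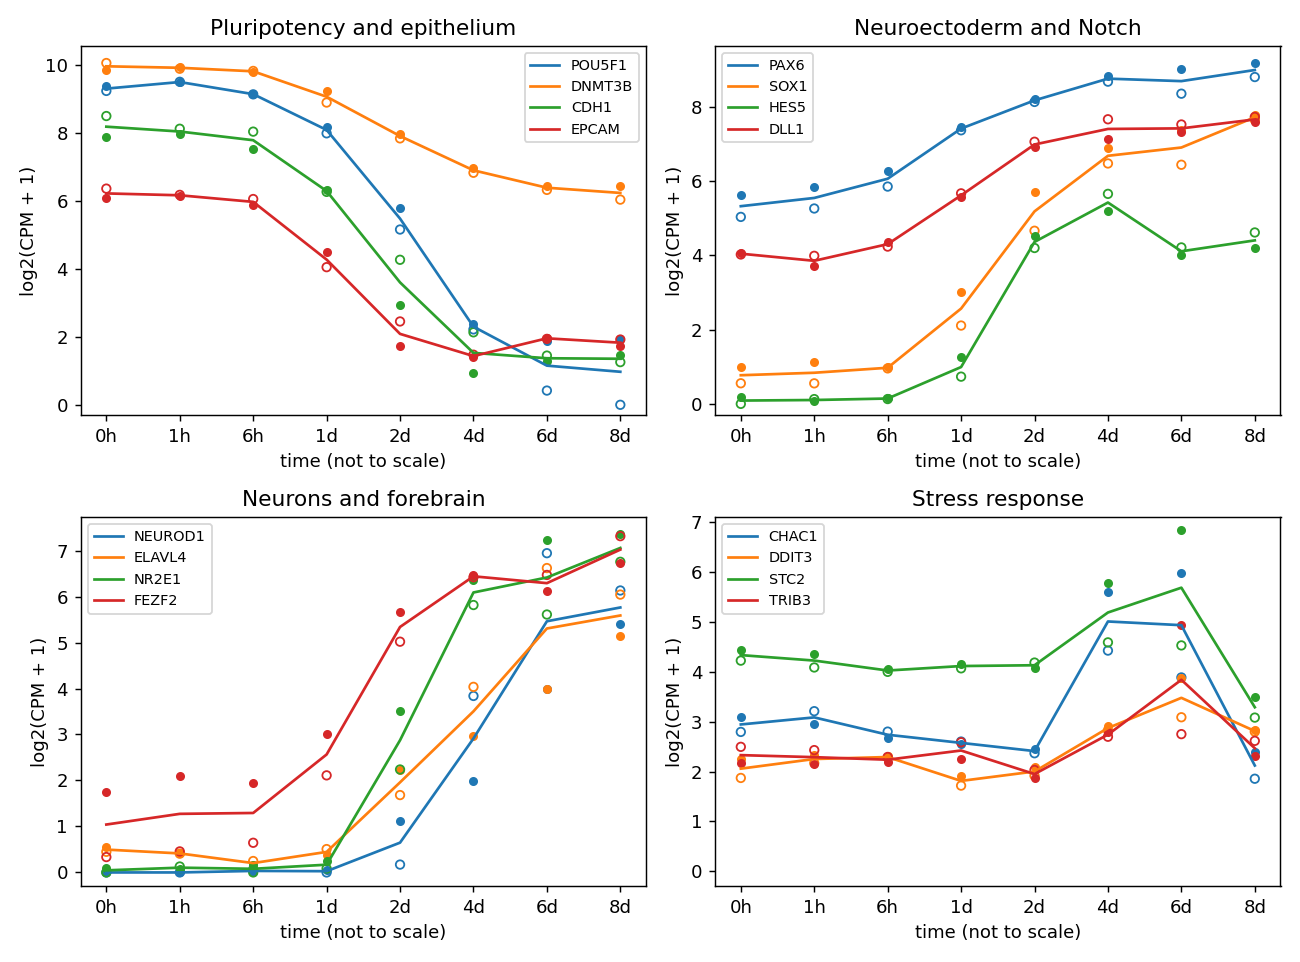
Expression of 16 genes over the 8 times, as log2 of CPM plus 1 on the y axis and time, not to scale, on the x axis; filled points are replicate 1, open points replicate 2 and lines join means of the log values. POU5F1 and CDH1 fall from 635 and 298 CPM at 0h to 1.42 and 1.57 at 8d, PAX6 rises to 515 CPM, and CHAC1, STC2 and TRIB3 part at 6d, where replicate 1 lies above replicate 2.

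Forebrain genes moved in both directions. FEZF2, a cortical patterning gene, rose by 6.74 ± 0.83 (adjusted p = 4e-05) and EMX2, a dorsal forebrain gene, by 5.38 ± 0.54. NR2E1 reached 135 ± 39 CPM, 4800-fold above 0h (counting interval 862 to 190000). HESX1, an early anterior gene, changed by −4.45 ± 0.31 (adjusted p = 4.4e-07). OTX2 stood at 425 ± 6.4 CPM at 0h and 306 ± 25 at 8d (−0.47 ± 0.14, adjusted p = 0.014, but 0.063, 0.05 and 0.095 without 0h replicate 1, 0h replicate 2 and 8d replicate 1, and 0.058 with library size scaling). Altogether 7 of 13 forebrain and eye field genes rose and 3 fell (9 and 4 over the list alone, adjusted p = 0.12), with 1 fall without either 0h library. The eye field genes RAX and SIX6 differed between the replicates, at 117 and 29.4 CPM in 8d replicate 1 and 9.87 and 0.948 in 8d replicate 2. Of 11 genes of midbrain, hindbrain and spinal cord 3 rose and 2 fell (4 and 2 over the list alone, adjusted p = 0.92), among them IRX3 at −2.64 ± 0.41. Rises and falls numbered 2 and 1 without 0h replicate 1, 1 and 2 without 0h replicate 2, and 1 and 1 without 8d replicate 2.

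Many neuronal and some neural crest genes were higher at 8d than at 0h, and some surface ectoderm genes were lower. NEUROD1 (chromosome 2, 181673088 to 181680876, minus strand) stood at 55 ± 20 CPM, at least 604-fold above 0h. ELAVL4 rose to 49.5 ± 22 CPM (6.9 ± 0.91), ELAVL3 by 5.58 ± 0.9 and MAP2, a dendritic protein, from 136 ± 12 to 442 ± 21 CPM. In total 12 of 13 neuron genes rose (adjusted p = 1.8e-05, and adjusted p = 0.62 with an estimated correlation), with GAP43 not passing. SOX10 stood at 44.7 ± 5.7 CPM (3.27 ± 0.55), among 7 of 11 crest and placode genes that rose (9 over the list alone). That list's adjusted p was 0.038, and adjusted p = 0.68 with an estimated correlation, 0.056 without 0h replicate 1 and 0.073 with library size scaling; 3 genes passed without 0h replicate 2. KRT7 fell from 22.1 ± 0.7 to 0.107 ± 0.072 CPM and IGFBP3 changed by −5.45 ± 0.59. Of 11 genes of non-neural ectoderm and amnion 6 fell and 1 rose (1 and 8 over the list alone, adjusted p = 0.0044, and adjusted p = 0.62 with an estimated correlation). The rise was ISL1 (6.23 ± 1.25), which neurons and placodes also express.

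Lists of other germ layers did not pass at 8d. Some of their members fell below the count filter and were not tested. Among these were SOX17, FOXA2, GATA4 and HNF4A of endoderm (2, 10, 20 and 35 counts over all libraries). Of mesendoderm, MIXL1, MSGN1, CER1 and GATA6 were left out (67, 3, 43 and 28 counts). Of 7 mesendoderm genes 2 rose, with WNT3 at 1.74 ± 0.35, and 1 fell (adjusted p = 0.92), with 1 rise without any single 0h, 1h, 6h, 1d or 8d library. Of 6 endoderm genes 3 rose, with CXCR4, a chemokine receptor that many cells use, at 4.52 ± 0.5, and 2 fell (adjusted p = 0.74); 1 rose without 0h replicate 2 or 8d replicate 2. Of 10 mesenchyme genes 3 rose, with POSTN, a matrix protein, at 4.48 ± 0.67, and COL1A1 fell, at −1.38 ± 0.2 (adjusted p = 0.39).

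Epithelial junction genes were low at 8d and Notch pathway genes high. EPCAM (chromosome 2, 47345158 to 47387601, plus strand) fell from 74.2 ± 10 to 2.56 ± 0.32 CPM and CDH1 (chromosome 16, 68737225 to 68835548, plus strand) from 298 ± 91 to 1.57 CPM. CLDN6, a tight junction protein, changed by −6.44 ± 0.33 and ESRP1, an epithelial splicing factor, by −8.97 ± 0.67. Of the 10 junction genes 8 fell and CLDN4 and TJP1 did not pass (camera adjusted p = 2.7e-10). DLL1 rose from 15.6 ± 0.34 to 202 ± 14 CPM (3.7 ± 0.18, adjusted p = 4.7e-08), LFNG by 2.52 ± 0.16, and HES5 (chromosome 1, 2528745 to 2530245, minus strand) peaked at 42.6 ± 9.9 CPM at 4d and stood at 20.5 ± 4.5 CPM at 8d. Of 11 Notch genes 10 rose, all but NOTCH1 (adjusted p = 1.9e-11). These lists, pluripotency and neuroectoderm held with an estimated correlation. Of 17 cell cycle genes 7 fell, with BUB1 at −1.45 ± 0.19 and MCM5 at −1.03 ± 0.12 (adjusted p = 0.019, and adjusted p = 0.73 with an estimated correlation, 0.061 without 0h replicate 1 and 0.15 without 8d replicate 2).

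**Figure D3:**
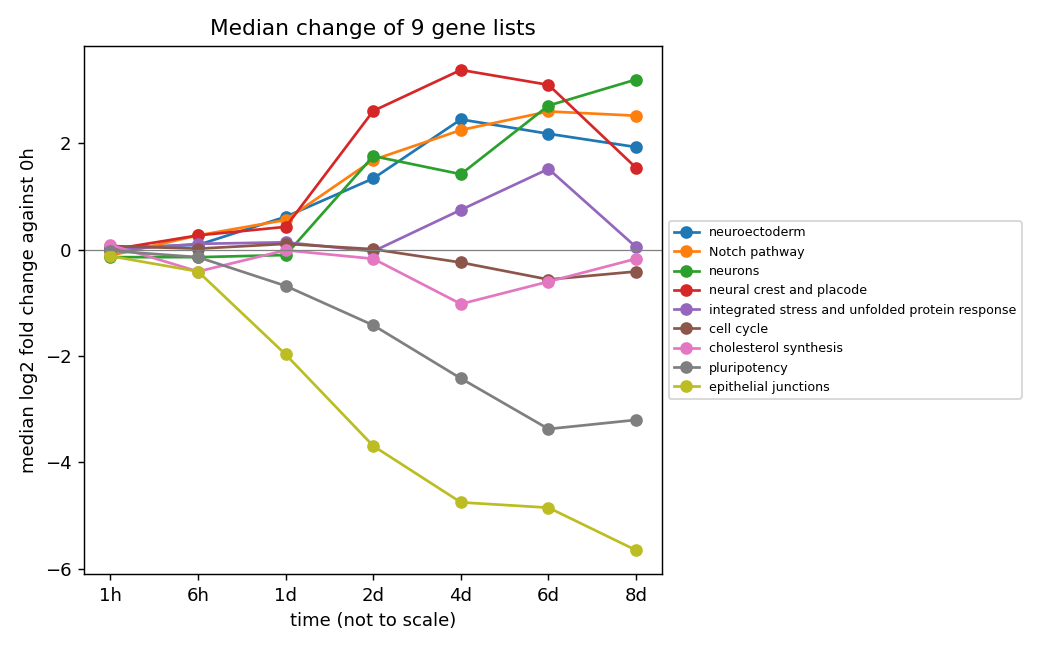
Median log2 fold change against 0h of the tested members of 9 gene lists (y axis) at the 7 later times, not to scale (x axis); lines join the medians, with members at 3 or fewer counts in a group set at their bound. At 8d the medians were −5.65 for epithelial junctions, −3.2 for pluripotency, 3.2 for neurons and 2.52 for the Notch pathway, and the integrated stress list stood at 1.52 at 6d and 0.05 at 8d.

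Targets of signalling pathways moved in both directions at 8d, and none of these lists passed. Of 11 WNT targets 5 rose, LEF1 by 2.69 ± 0.23 and LGR5 by 4.61 ± 0.46, and DKK1, a secreted WNT inhibitor, fell, at −2.7 ± 0.4 (6 and 3 over the list alone, adjusted p = 0.16). Of 12 FGF and ERK targets 6 rose and 4 fell (adjusted p = 0.92), with SPRED2 at 1.87 ± 0.21 and ETV4 at −4.45 ± 0.37. Of 10 BMP targets 4 rose and 1 fell (adjusted p = 0.45), with SMAD9 at 2.86 ± 0.36 and ID2 at −1.07 ± 0.17. Of 8 Nodal and TGF-beta targets 2 rose and 4 fell (adjusted p = 0.92), with SKIL at 1.33 ± 0.14. YAP and SRF targets had 4 of 15 higher, CCN2 by 3.12 ± 0.27, and 6 lower (5 and 6 over the list alone, adjusted p = 0.92). Without any single 0h or 8d library 3 WNT targets rose, and 2 and 3 of them fell without a 4d and a 6d library.

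Stress and metabolic lists did not pass at 8d either. Of 15 immediate early genes 6 rose, ATF3 by 2.91 ± 0.28 and JUN by 2.18 ± 0.31 (adjusted p = 0.088), and 1 also fell without 8d replicate 2. Of 14 integrated stress genes 3 rose (1 over the list alone, adjusted p = 0.92), DDIT4 among them; 1 rose and 1 fell without 0h replicate 2 or 8d replicate 1, and 5 rose and 2 fell without either 6d library. Heat shock genes went both ways, with 3 of 10 higher (HSPA1A 1 ± 0.18) and 3 lower (HSPD1 −0.9 ± 0.16), 4 lower over the list alone (adjusted p = 0.92); 1 rose without 0h replicate 1. Of 13 p53 targets 3 rose, TP53INP1 by 1.78 ± 0.2, and 2 fell, with BAX at −1 ± 0.12 (adjusted p = 1). Cholesterol synthesis had 2 of 17 lower (1 over the list alone, adjusted p = 0.49), led by SC5D (−1.52 ± 0.18), with 1 lower without any single 0h, 1h, 2d, 4d or 8d library and 5 without either 6d library. Of the genes that follow RNA quality, 6 of 9 mitochondrial transcripts fell (8 over the list alone, adjusted p = 0.055), with 1 lower without 0h replicate 1 or 8d replicate 2 and 2 without 8d replicate 1. Of 10 ribosomal protein genes and 5 metallothionein and zinc export genes 0 passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 (adjusted p = 0.73 and 0.92).

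Of all tested genes 7403 (43.1%) passed at 8d (3767 higher, 3636 lower; 4130 by at least 1 on the log2 scale). Library size scaling moved the median of all genes from 0.01 to 0.15 and the higher share from 50.9% to 63.3%. The share was 48.9% with RLE factors, 46.9% with the length trend removed and 47.2% with the GC trend removed. From 6d to 8d 27 genes passed, 15 higher and 12 lower. SPARC, a matrix glycoprotein, rose from 293 ± 40 to 634 ± 30 CPM (1.11 ± 0.11, adjusted p = 0.0026), and EGLN3, an oxygen-sensing hydroxylase, fell from 32.5 ± 1.8 to 13.8 ± 0.11 CPM (−1.24 ± 0.12, adjusted p = 0.0026). WNT7A rose from 2.54 ± 0.93 to 26 ± 1.7 CPM (adjusted p = 0.029), and CHAC1 fell from 38 ± 34 to 3.42 ± 1.1 CPM (adjusted p = 0.042), but these lost their calls under single omissions, up to 0.16 and 0.4. The count was 5 and 6 without 8d replicate 1 and 2, 7 without either 0h library, 16 without either 1h library, 6 without either 6h or 2d library and 934 without 6d replicate 2. A fit on the 4 libraries of 6d and 8d gave 0 in edgeR (555 at an unadjusted p under 0.05), DESeq2 175 and no low-count filter 579. With the GC trend removed 43.6% of calls were higher, against 55.6%.

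The single-cell library at 8d held 9363 cells in 5 clusters that the authors numbered 0 to 4 without names. Cluster 0 held 37.1% of cells (95% exact binomial interval 36.1 to 38.0), cluster 1 27.8% (26.9 to 28.8), cluster 2 25.4% (24.5 to 26.3), cluster 3 6.1% (5.62 to 6.6) and cluster 4 3.64% (3.27 to 4.04); the intervals cover counting error only. Median UMIs (distinct RNA molecules) per cell were 4604, 5602, 4884, 6957 and 5017 in clusters 0 to 4, and median genes 2274, 2725, 2437, 3097 and 2482. The median mitochondrial share was 1.72% in cluster 1 and 3.27% in cluster 3. Over all cells the medians were 5050 UMIs, 2487 genes and 2.54% mitochondrial UMIs. With cells of at least 2000 UMIs alone, 8787 remained and the shares of clusters 0 and 1 were 35% and 29%. Expression per cell was not used here, so the clusters are not tied to the genes above, and with 1 library there is no test.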

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

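The fits on 6 libraries, the removal of trends and the joint omission of 3 libraries were chosen after seeing the data; all other alternatives were planned. The 220 called results for single named genes were chosen by rules that use these same data, such as large folds or small adjusted p. That choice favours stability beforehand. Of the 220, none turned its direction under any alternative. All kept their call with RLE factors, no filter, the stricter filter, the replicate block and the length trend removed. With library size scaling 217 did, with the GC trend removed 219, with DESeq2 218, with the 3 libraries left out 208 and with the 4 libraries of a comparison alone 202. In every single omission 174 kept their call, and the most were lost without 0h replicate 2 (27) and 1d replicate 2 (25). A left-out fit leaves 1 time with a single library, which is assumed to vary like the others. For calls lost by name the cause was not tested.

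Counts of changed genes within 1.5 times the reported one are not listed. Without a low-count filter, which tests more genes of low count, edgeR called 12 at 1h, 43 at 6h, 1805 at 1d, 56 for 6h vs 1h, 1090 for 1d vs 6h, 1441 for 2d vs 1d, 1462 for 4d vs 2d, 1605 for 6d vs 4d and 579 for 8d vs 6d. DESeq2 gave 4 at 1h, 1210 at 1d, 13 for 6h vs 1h, 578 for 1d vs 6h, 842 for 2d vs 1d, 971 for 4d vs 2d, 836 for 6d vs 4d and 175 for 8d vs 6d. The 4 libraries alone gave 3521 at 6d, 5 for 6h vs 1h, 70 for 1d vs 6h, 340 for 4d vs 2d, and 0 for both 6d vs 4d and 8d vs 6d, with fewer libraries to estimate the spread. With the 3 libraries left out the counts were 348 at 1d, 4583 at 2d, 71 for 1d vs 6h, 1344 for 4d vs 2d, 1030 for 6d vs 4d and 17 for 8d vs 6d; at 4d, 6d and 8d they were 6970, 7027 and 7907. The 6 early libraries gave 3 for 6h vs 1h. For the differences between tools and filters the cause was not tested.

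Replicates share numbers across times, but the numbers are not known to pair the samples. In 18 of 28 pairs of times the deviations of same-numbered libraries correlated above 0.1 across genes (range −0.09 to 0.51, median 0.11). The highest values were those of 6d with 8d (0.51) and 4d with 6d (0.39), so late libraries of the same number shared a difference that the main fit ignores. With the replicate number as a block edgeR called 1008 genes at 1d, 382 for 1d vs 6h, 699 for 2d vs 1d, 846 for 4d vs 2d, 551 for 6d vs 4d and 54 for 8d vs 6d, and 2 lists passed at 1h; WNT targets at 4d had an adjusted p = 0.063. The 6 early libraries with the block gave 12 at 1h, 149 at 6h and 140 for 6h vs 1h.

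Leaving out each library in turn gave no called gene in any case at 1h, at 6h or for 6h vs 1h (0 to 0). The range was 56 to 1534 at 1d, 1460 to 3713 at 2d, 3209 to 6074 at 4d, 4691 to 7205 at 6d and 5367 to 8272 at 8d. Between neighbouring times it was 0 to 999 for 1d vs 6h, 89 to 901 for 2d vs 1d, 149 to 981 for 4d vs 2d, 18 to 1547 for 6d vs 4d and 5 to 934 for 8d vs 6d. Genes that varied at any time numbered 7632 to 10413.

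Camera's count of called lists was 1, 4, 8, 9, 11, 13 and 8 from 1h to 8d. With an estimated correlation it was 0 at 1h, 0 at 6h, 2 at 1d, 4 at 2d, 4 at 4d, 3 at 6d and 4 at 8d. At 1h it was 3 with the length trend removed and 4 with the 3 libraries left out. Single omissions gave 0 to 3 at 1h, 3 to 6 at 6h, 8 to 9 at 1d, 9 to 13 at 2d, 10 to 13 at 4d, 9 to 16 at 6d and 6 to 10 at 8d. Without the 3 libraries neural crest and WNT targets at 1d had adjusted p-values of 0.26 and 0.2 and the mitochondrial genome 0.55. At 4d WNT targets had 0.072, and at 6d non-neural ectoderm, cholesterol synthesis and basement membrane had 0.12, 0.19 and 0.083.

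With cells of at least 2000 UMIs the share of cluster 0 was 35% and of cluster 1 29%, and the shares of the others stayed within their intervals. A limit of 10% mitochondrial UMIs and the removal of doublets each removed 0 cells. The deposited cells all lay below that limit and were all singlets, so these 2 settings say nothing of stability. Depth limits the folds of genes with few counts at 0h or 8d, such as NR2E1, SST and IDO1, whose counting intervals span more than a factor of 100 from end to end.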

Other observations

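Of the tests in this part, those of ribosomal protein genes and that of 6d replicate 1 alone were chosen after the result was seen, and the fits on 6 libraries and the removal of length and GC trends were added after seeing the data. Genes of retinoic acid handling moved apart at 8d. RARB rose from 0.607 ± 0.39 to 17.3 ± 3.9 CPM (log2 fold change 4.77 ± 0.4, edgeR adjusted p = 1.8e-06, n = 2). CYP26A1, which degrades retinoic acid, fell from 60.6 ± 5.6 to 0.107 ± 0.072 CPM (−8.96 ± 0.81, adjusted p = 3.1e-06), and CYP26C1, a related enzyme, was 760-fold lower (counting interval 136 to 30100, 1 count at 8d). ALDH1A2, which makes retinoic acid, went from 30.8 ± 1.4 to 4.24 ± 0.073 CPM (−2.86 ± 0.29). Of 10 genes of this list 3 rose and 5 fell (camera adjusted p = 0.15), and 1 rose without 0h replicate 2. Basement membrane genes likewise had 5 of 12 higher, with FN1 at 2.36 ± 0.15 and COL4A5 at 1.94 ± 0.19, and 3 lower, with LAMB1 at −1.55 ± 0.33 (adjusted p = 0.12). Of 16 hypoxia and glycolysis genes 6 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.73). ADM, a vasodilator peptide, went from 28.2 ± 1.6 to 0.452 ± 0.087 CPM and EGLN3 from 71.6 ± 1.9 to 13.8 ± 0.11, while NDRG1 rose by 2.72 ± 0.54 and the glycolysis regulator PFKFB3 from 39.7 ± 0.95 to 89.6 ± 5.1 CPM. Without 0h replicate 2 there were 2 rises and 3 falls in this list, and without 8d replicate 2 there were 3 and 3.

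Some genes used as markers of neural tissue were already present at 0h. PAX6 stood at 48.1 and 31.9 CPM in the 0h replicates, SIX3 at 86.7 and 130, OTX2 at 430 and 421 and CDH2 at 367 and 398, beside POU5F1 at 635 ± 43 CPM. NANOG, a core stem cell factor, was at 4.53 and 3.08 CPM at 0h. It had 1 to 2 counts in all at 2d, 4d and 6d, and stood at 0.158 and 0 CPM in the 8d replicates.

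At 1h fewer genes had a small p than chance gives (389 against 858). With the 6 libraries of 0h, 1h and 6h alone 820 genes had an unadjusted p under 0.05 for 1h against 0h. Chance gives 803 there, so a spread estimate drawn from later and more variable times may account for part of the shortfall. The 4 libraries of 0h and 1h alone, which hold no later time, gave 641 such genes. The later times therefore need not be the whole cause. For 6h against 0h the 6 libraries gave 1738 such genes against 803 by chance, though none passed after adjustment. The 4 libraries of 0h and 6h alone gave 1421. The count of 837 at 6h from all 16 libraries may therefore understate early change. With the replicate number as a block the 6 libraries gave 149 called genes at 6h. A difference between replicate numbers that the early times share may therefore also hide early changes. Both explanations remain open together. DESeq2 on all libraries called 0 genes at 6h. It too drew its spread from all times and had no replicate block, so this cannot weigh against either.

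The 10 ribosomal protein genes lay lower in replicate 1 than in replicate 2 at 6d (median log2 difference −0.89, range −2.54 to −0.62) and at 8d (−0.51). Other genes matched on GC content and level gave 0.039 times the ribosomal difference at 6d and −0.16 times at 8d, which argues against GC content as the whole cause. Genes matched on transcript length gave 0.24 times at 6d (128 genes, median −0.21, quartiles −0.45 to −0.02). At 8d they gave −0.11 times (median 0.06, quartiles −0.19 to 0.18). Both ratios lay under the limit set for reading them against length. At 6d, however, the lower quartile of the matched genes was too low for a second condition on their spread. Over all genes, the difference of replicate 1 from replicate 2 rose with transcript length at 6d and 8d (Spearman correlation 0.24 and 0.16). It fell with GC content by a similar degree (−0.23 and −0.11), so a part for GC content stays open as well. A loss of short transcripts therefore stays open. At 8d the length-matched genes were not lower in replicate 1, so only the trend over all genes goes with it there. The annotated lengths (median 1110 bases for these genes) exceed those of the mature ribosomal mRNAs, which weakens the length test. A difference between the cultures was not tested, since the labels say nothing of them.

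Of 14 integrated stress response genes 7 were higher at 4d than at 0h and 11 at 6d, and the 6d replicates stood apart. With an estimated correlation the list passed at neither time (camera adjusted p = 0.73 at 4d and 0.53 at 6d). Without 6d replicate 1, 6 of the list's genes were called at 6d (median 0.64 against 1.52), so its part at 6d cannot be told apart from that of the time. With the length or the GC trend removed at least 11 genes were called at 6d, which argues against these trends. At 4d the count was 4 without 4d replicate 1 and 5 without 4d replicate 2. The cause of the rise was not tested further.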
